A study of Mus musculus with 6 samples.

How the data were processed

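RNA from sorted splenic Tfh cells of 6 samples, 3 labelled Cbl-/-Cbl-b-/- and 3 labelled control, had been sequenced after injection of NP-OVA. The deposited table lists 47729 genes by Ensembl identifier with 1 column per library. The values are a normalised signal: read counts per gene divided by 1 size factor per library, by the authors, per the file headers and the values. The submitters' processing notes name STAR 2.5.1b, featureCounts 1.4.6, DESeq2 1.12.3 and genome build GRCm38, without saying what each was used for; the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Without a known strand setting, reads of overlapping genes and antisense partners may be mixed, and near-identical copies such as Hba-a1 and Hba-a2, gene families and receptor V segments share reads. The same deposited table gives the authors' comparison, per the file headers: mean values, log2 fold changes with their standard errors, a test statistic (score) and p-values. Those were used only as an alternative.

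Every value of a library was a whole multiple of the smallest value above 0 in its column (100% of values within a tolerance of 0.001 of a read), so whole reads were recovered by dividing by that value. Library totals were 23392254 to 38368885 reads assigned to genes, and the size factors ranged from 0.73 to 1.22. The labels say that the 6 samples are separate but not that each came from a separate mouse, so p-values measure the spread between these samples. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom between 10.5 and 95.2), and each was counted as 1 replicate. The first principal component took 45.4% of the variance and separated the genotypes.

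Genes with a deposited value of at least 10 in at least 3 of the 6 libraries were kept (13602 genes). Since the values are not raw counts, the main test was limma-trend 3.58.1 in R 4.3.3 on log2(value + 1), with genotype as the only term. It was two-sided, with Benjamini-Hochberg adjustment over the genes kept and a threshold of 0.05. On simulated counts drawn from these libraries' means, depths and dispersions, with 200 of 13337 genes changed, each with a mean of at least 50, the test recovered 67% of 100 genes changed by a log2 of 1 and 96% of 100 changed by a log2 of 2, with 14 false calls. The biological coefficient of variation was 0.22 (edgeR common estimate). Before the data were examined, 30 lists of genes for T cell states, signalling, metabolism, RNA quality and other cell types were written from general knowledge. The 29 lists with at least 5 kept members were tested with limma's camera at a preset correlation of 0.01 and adjusted over lists; camera with an estimated correlation, fry and camera on ranks were alternatives. Of 614 list entries, 612 matched a gene row. Per list, members past the threshold were also counted with adjustment over the list alone.

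The genes named were set by a rule fixed before the data were examined: Cbl and Cblb; a core of 8 genes (Bcl6, Cxcr5, Pdcd1, Icos, Il21, Cd40lg, Maf, Prdm1); the 8 largest rises and 8 largest falls past the threshold with no overlap between groups and a mean of at least 50 in the higher group, leaving out receptor segments, predicted genes and pseudogenes; and up to 4 members of each list by smallest p, or up to 2, given as values, where none passed. Results of some genes under this rule are withheld and not reported. Names outside this rule (Foxp3, Hspa1a, Egr1, Ier2, Nr4a2 and Cd69 among them) were chosen after their values were seen. In the report these are members of fixed lists, and in the closing section most are in no list. Coordinates come from GENCODE release M21 on GRCm38, matched by Ensembl identifier for 13557 of the 13602 genes tested. Where the lower group had 1 to 3 reads in all, the ratio of reads is given with an exact conditional 95% interval for counting error.

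Alternatives fixed before the data were examined were edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, the authors' comparison, pseudocounts of 0.5 and 10, no filter and a filter at 50, TMM and quantile scaling, library weights, the replicate number as a block, receptor segments left out, and each library left out in turn. Leaving out genes on X and Y, and genes within 5 Mb of Cbl or Cblb, was added after the data were seen. Other tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.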

Results

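Follicular helper T (Tfh) cells are the CD4 T cells that help B cells in the germinal centre, and they are marked by the chemokine receptor CXCR5 and the checkpoint receptor PD-1. RNA was sequenced from Tfh cells sorted from mouse spleen as CD4, TCR beta, PD-1 high and CXCR5 high after intraperitoneal injection of the hapten-carrier antigen NP-OVA. The series asks how the CBL ubiquitin ligases, acting downstream of the costimulatory receptor ICOS, bear on the Tfh programme. It holds 6 libraries, 3 labelled Cbl-/-Cbl-b-/- (double knockout) and 3 labelled control. The values are normalised read counts, from which whole reads could be recovered. Reads assigned to genes came to 30528775, 38368885 and 36022153 in double knockout replicates 1 to 3. They came to 31041479, 23392254 and 35075509 in control replicates 1 to 3. The most abundant gene took between 1.13% and 1.46% of a library's reads. Mean values are given with the SD over n = 3 libraries per group. Fold changes are double knockout minus control on the log2(value + 1) scale, which understates the change of genes with low values.

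The targeted genes were read first. Cbl (ENSMUSG00000034342, GRCm38 chromosome 9, 44142976 to 44234049) encodes an E3 ubiquitin ligase that restrains antigen receptor signalling. Its normalised counts were 3262, 3856 and 2221 in the 3 double knockout libraries and 12417, 12945 and 8614 in the 3 controls, a log2 fold change of -1.88 ± 0.23 (SE) with a limma adjusted p of 0.00888. Cblb (ENSMUSG00000022637, chromosome 16, 52031225 to 52208048), the related ligase that sets the threshold for CD28 costimulation, stood at 7459, 7881 and 8054 against 8943, 10037 and 6955, a log2 fold change of -0.13 ± 0.14 (adjusted p = 0.703). These are totals over whole genes, and the deleted part of either gene is not given in the sources used here, so the Cblb total does not check its label. The call for Cbl ended without control replicate 1 (log2 fold changes of -2.06 to -1.65 with each library left out in turn, largest adjusted p = 0.0524).

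**Figure D1:**
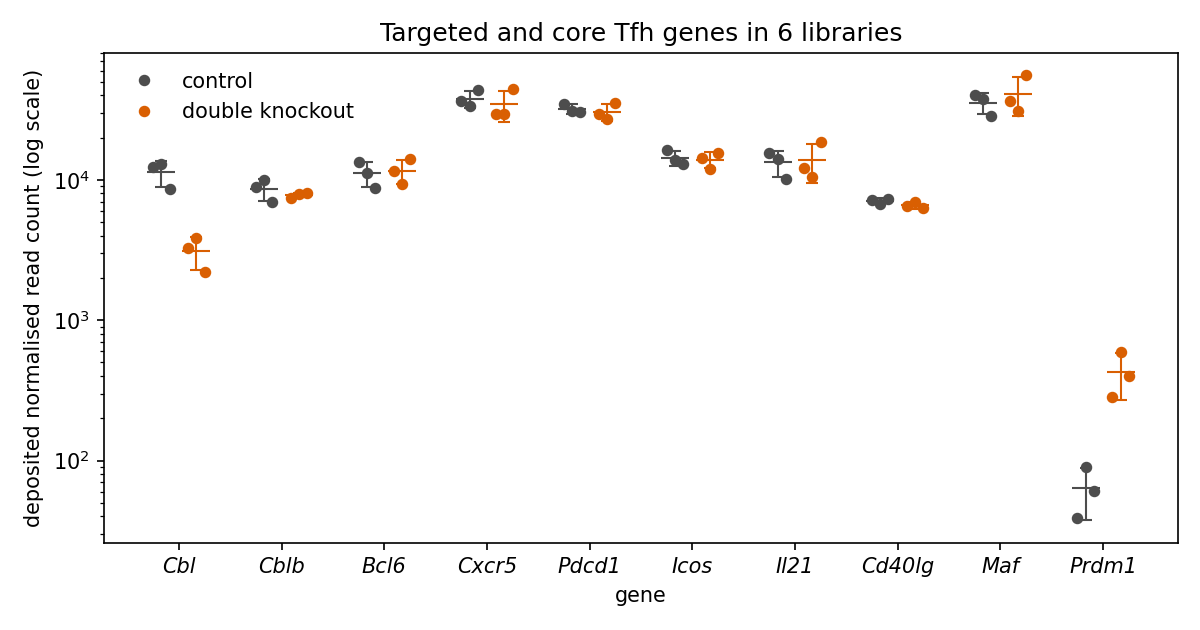
Normalised read counts (log axis) of the targeted genes Cbl and Cblb and of the core Tfh genes in each library; each point is a library, the bars are the mean ± SD of 3 libraries, grey for control and orange for double knockout. Cbl lies below and Prdm1 above the control libraries in all 3 double knockout libraries, while the points of Bcl6, Cxcr5, Pdcd1, Icos, Il21 and Maf overlap.

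In the comparison of double knockout with control Tfh cells, 398 of 13602 genes differed, 252 higher and 146 lower in the double knockout (limma, adjusted p below 0.05). Of the Tfh core, only Prdm1, which encodes the BCL6 antagonist BLIMP1, passed, and it was 6.73-fold higher. For the other core genes, not passing does not show equal levels. The cells were sorted as PD-1 high and CXCR5 high, so like levels of Pdcd1 and Cxcr5 may follow from the sort. With camera at its preset correlation, the lists of interferon-stimulated, Th1 and cytotoxic, and regulatory T cell genes shifted up, and the lists of T cell receptor early response genes and of heat shock and dissociation stress genes shifted down. With an estimated correlation none of these lists passed (adjusted p from 0.454 to 0.665), and the regulatory T cell list lost its call without double knockout replicate 2 (median 0.07, adjusted p = 0.216). On the log2(value + 1) scale the largest differences among genes that passed were those of sex-linked transcripts. The 4 Y-linked genes named below had next to no reads in the double knockout libraries, and Xist was high in them. By these transcripts sex went with genotype, so no difference in this report can be assigned to genotype alone. The count of 398 depended on which libraries were tested. It was 58 without control replicate 1, 69 without double knockout replicate 1 and 117 without control replicate 2. It was 232 without control replicate 3, 310 without double knockout replicate 3 and 498 without double knockout replicate 2. Such fits have fewer libraries and less power, so a lost call alone does not show that it rested on that library. Of the named genes that stayed in the test in all 6 of these fits, Id2, Cxcr3, Nr4a1, Cd247, Oas3 and Trdc passed in each of them, and the others that had passed lost the call in at least 1. Count-based tests on the same reads gave 405 genes with edgeR and 1036 with DESeq2.

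Bcl6 (ENSMUSG00000022508, chromosome 16, 23965052 to 23988852), the transcription factor that defines Tfh cells, had 11653 ± 2310 normalised counts in the double knockout and 11121 ± 2269 in the control (log2 fold change 0.07, 95% confidence interval -0.37 to 0.51, limma adjusted p = 0.907). Cxcr5 had 34460 ± 8762 against 37681 ± 5191 (-0.15 ± 0.19). Pdcd1, which encodes PD-1, had 30581 ± 4384 against 32026 ± 2457 (-0.07 ± 0.13), and Icos had 13926 ± 1782 against 14327 ± 1748 (-0.04 ± 0.13). Il21, the main Tfh cytokine, had 13762 ± 4324 against 13308 ± 2813 (0.03 ± 0.24). Cd40lg had 6577 ± 347 against 7123 ± 297 (-0.12 ± 0.09) and Maf 41162 ± 12857 against 35560 ± 6094 (0.18 ± 0.23). None of these 7 genes passed the test (adjusted p from 0.588 to 0.974). The signs of Bcl6, Pdcd1, Icos, Il21 and Maf turned when single libraries were left out. Prdm1 (ENSMUSG00000038151, chromosome 10, 44437177 to 44528501) had 427 ± 155 against 63.3 ± 25.9 (2.75 ± 0.37, limma adjusted p = 0.0127). Every double knockout library lay above every control. The call for Prdm1 ended without control replicate 1 (adjusted p = 0.0504).

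Of the 32 genes of the Tfh programme list, 5 fell, none rose and 27 did not pass the test. Adjusted over the list alone, 10 fell and 3 rose. The members that fell were P2rx7, an ATP receptor that limits Tfh numbers, with 14468 ± 910 against 24935 ± 692 (log2 fold change -0.79 ± 0.10), Egr3 (-0.92 ± 0.15), the adhesion receptor Slamf6 (-0.82 ± 0.13), the inhibitory receptor Tigit (-0.56 ± 0.11) and the chemokine receptor Cxcr4 (-0.89 ± 0.17), with limma adjusted p between 0.0101 and 0.0359. With each library left out in turn, Cxcr4 lost its call in 5 of 6 fits, Tigit in 4, Egr3 and Slamf6 in 3 and P2rx7 in 2. The list as a whole shifted down by a median of -0.11 (camera adjusted p = 0.0117; adjusted p = 0.532 with an estimated correlation). Its call ended without double knockout replicate 2 (adjusted p = 0.13), with quantile scaling (adjusted p = 0.0512) and with camera on ranks (adjusted p = 0.0747). With each library left out in turn the list median ran from -0.20 to -0.06. Among 17 genes that oppose BCL6 or mark egress from follicles, Prdm1 and Id2 rose, and the other 15 did not pass. Adjusted over the list alone, 3 rose and 3 fell. The third that rose was Il2ra (1.64 ± 0.51). Those that fell were S1pr1 (1996 ± 1260 against 5445 ± 1231, -1.62 ± 0.42), Klf2 (1182 ± 682 against 2957 ± 458, -1.47 ± 0.36) and Gpr183 (-0.76 ± 0.17). Id2, an inhibitor of E proteins that favours Th1 over Tfh fate, had 3444 ± 631 against 1336 ± 110 (1.35 ± 0.15, limma adjusted p = 0.00733). The BCL6-opposing list was not shifted in 1 direction (median -0.17, mean 0.21, camera direction down, adjusted p = 0.922). Its members moved both ways, 8 with positive and 9 with negative fold changes.

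Genes of other helper fates were higher in part. The gamma-delta and NKT cell list given below was higher as well (median 1.72, camera adjusted p = 9.85e-05, 0.454 with an estimated correlation). Which cells these transcripts came from was not tested here. Of 21 Th1 and cytotoxic genes, 4 rose and none fell (7 rose and 2 fell when adjusted over the list alone), with a list median of 0.88 (camera adjusted p = 0.000496; adjusted p = 0.6 with an estimated correlation). The Th1 and cytotoxic list kept its preset-correlation call with each library left out in turn (median from 0.62 to 1.35). The chemokine receptor Cxcr3 rose, with 1982 ± 191 against 575 ± 90.7 (log2 fold change 1.79 ± 0.15, limma adjusted p = 0.00249). The granzymes Gzma (1.81 ± 0.30) and Gzmb (2.76 ± 0.54) and the transcription factor Zeb2 (2.38 ± 0.46) rose as well. Cxcr3 passed with each library left out in turn, whereas Gzma, Gzmb and Zeb2 each lost the call in 4 or more of those 6 fits. Cxcr3 lies on chromosome X, and the sex pattern given below followed the genotype groups, so its rise cannot be separated from sex. Of 10 Th17 genes, Ahr alone rose (300 ± 94.8 against 89.6 ± 20.5, 1.70 ± 0.30; 5 rose over the list alone). Ahr lost its call with the replicate number as a block (adjusted p = 0.0593). The list median was 1.16 (camera adjusted p = 0.0051; adjusted p = 0.46 with an estimated correlation). Of 9 Th2 genes, Il17rb fell (-2.17 ± 0.38) and the list was not shifted (median 0.24, camera adjusted p = 0.511; 1 rose and 1 fell over the list alone).

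Of 18 regulatory T and follicular regulatory T cell genes, 3 rose and none fell (6 rose and 1 fell over the list alone). The median was 0.62 (camera adjusted p = 0.00307; adjusted p = 0.6 with an estimated correlation). The decoy receptor Il1r2 had 1615 ± 546 against 471 ± 62.7 (log2 fold change 1.72 ± 0.25), the costimulatory receptor Tnfrsf4 3879 ± 963 against 1659 ± 93.7 (1.20 ± 0.17) and Capg 2344 ± 418 against 1231 ± 180 (0.93 ± 0.16), with limma adjusted p between 0.0157 and 0.0274. Foxp3, the defining factor of regulatory T cells, stood at 5451 in double knockout replicate 2 and between 149.6 and 768 in the other 5 libraries. Without that replicate the list median was 0.07 (camera adjusted p = 0.216). Among 13 co-inhibitory receptors, Cd160 (-0.92 ± 0.14), Tigit and Cd200r1 (-1.45 ± 0.28) fell and none rose (2 rose and 3 fell over the list alone). The list was not shifted (median -0.07, camera adjusted p = 0.554).

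Of 30 early response genes of the T cell receptor, 6 fell and 2 rose (9 and 4 over the list alone). The median was -0.33 and the list shifted down (camera adjusted p = 0.00282; adjusted p = 0.454 with an estimated correlation). The heat shock and dissociation stress list moved in the same direction, with a median of -0.40 (camera adjusted p = 0.0135; adjusted p = 0.665 with an estimated correlation). The nuclear receptor Nr4a1, a reporter of receptor signal strength, had 2399 ± 331 against 5582 ± 827 (log2 fold change -1.22 ± 0.14, limma adjusted p = 0.00882) and passed with each library left out in turn. Nr4a3 (-1.12 ± 0.18), Cd83 (-0.93 ± 0.13) and Egr3 (-0.92 ± 0.15) also fell, as did Egr1 and Ier2, while Nr4a2 and Cd69 rose. With each library left out in turn, Nr4a3 lost its call in 4 of 6 fits and Cd83 and Egr3 in 3. In the list of T cell receptor and costimulation signalling, Cd247, which encodes the zeta chain, fell from 23686 ± 2224 to 9086 ± 1317 (-1.39 ± 0.13, adjusted p = 0.00424). Ubash3b fell from 2134 ± 100.02 to 1127 ± 275 (-0.95 ± 0.17). The other 26 members did not pass, and over the list alone the same number fell, 2. The list itself was not shifted (median 0.01, mean -0.09, camera direction down, adjusted p = 0.574).

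Of 29 genes of PI3K, AKT and mTOR signalling, which lies downstream of ICOS, Pdk1 (0.80 ± 0.13) and Sesn3 (0.71 ± 0.14) rose and Ddit4 (-0.55 ± 0.09) fell (3 rose and 1 fell over the list alone), without a shift of the list (median 0.07, camera adjusted p = 0.498). Sesn3 lost its call without any single library. Of 20 E3 ligases and partners linked to T cell tolerance, Dtx1, an anergy-associated ligase, had 2803 ± 1569 against 11270 ± 1653 (log2 fold change -2.13 ± 0.33). Cbl fell too, while Socs3 (1.45 ± 0.25) and Rnf128 (0.63 ± 0.11), which encodes GRAIL, rose (the same counts over the list alone, 2 and 2; list median -0.02, camera adjusted p = 0.735). Rnf128, which lies on chromosome X, also lost its call without any single library. The series title names chaperone-mediated autophagy. Among its 16 listed genes, Ctsa, which encodes the protease that cuts the lysosomal receptor LAMP2A, had 10332 ± 929 against 6026 ± 417 (0.78 ± 0.11, limma adjusted p = 0.0129). It was the only member that passed, also over the list alone, where 1 rose, and the list did not pass (median -0.13, camera adjusted p = 0.132). It passed as lower without double knockout replicate 3 (median -0.27, adjusted p = 0.0193) and with library weights (median -0.24, adjusted p = 0.0338). None of 41 macroautophagy and lysosome genes passed, over all genes or over the list alone (median -0.02, camera adjusted p = 0.557). The smallest p belonged to Optn (726 ± 111 against 1254 ± 258) and Ulk1 (2208 ± 143 against 1725 ± 184). Optn passed as lower with DESeq2 (adjusted p = 0.00263), in the authors' deposited table (adjusted p = 0.0026), with library weights (adjusted p = 0.0101) and without double knockout replicate 2 (adjusted p = 0.0424), and Ulk1 as higher with library weights (adjusted p = 0.0364).

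All 26 interferon-stimulated genes had positive fold changes, 15 rose over all genes tested and 22 over the list alone. The median was 0.94 (camera adjusted p = 4.33e-21; adjusted p = 0.454 with an estimated correlation). The antiviral enzyme Oas3 had 4697 ± 955 against 1610 ± 312 (log2 fold change 1.54 ± 0.19) and passed with each library left out in turn. The nucleic acid sensors Zbp1 (0.92 ± 0.11) and Ifih1 (0.96 ± 0.12) and the abundant Ifi27l2a, with 16298 ± 1592 against 7171 ± 1347 (1.20 ± 0.15), rose as well, with limma adjusted p between 0.00882 and 0.0118. The list kept its call with each library left out (median from 0.82 to 1.03).

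**Figure D2:**
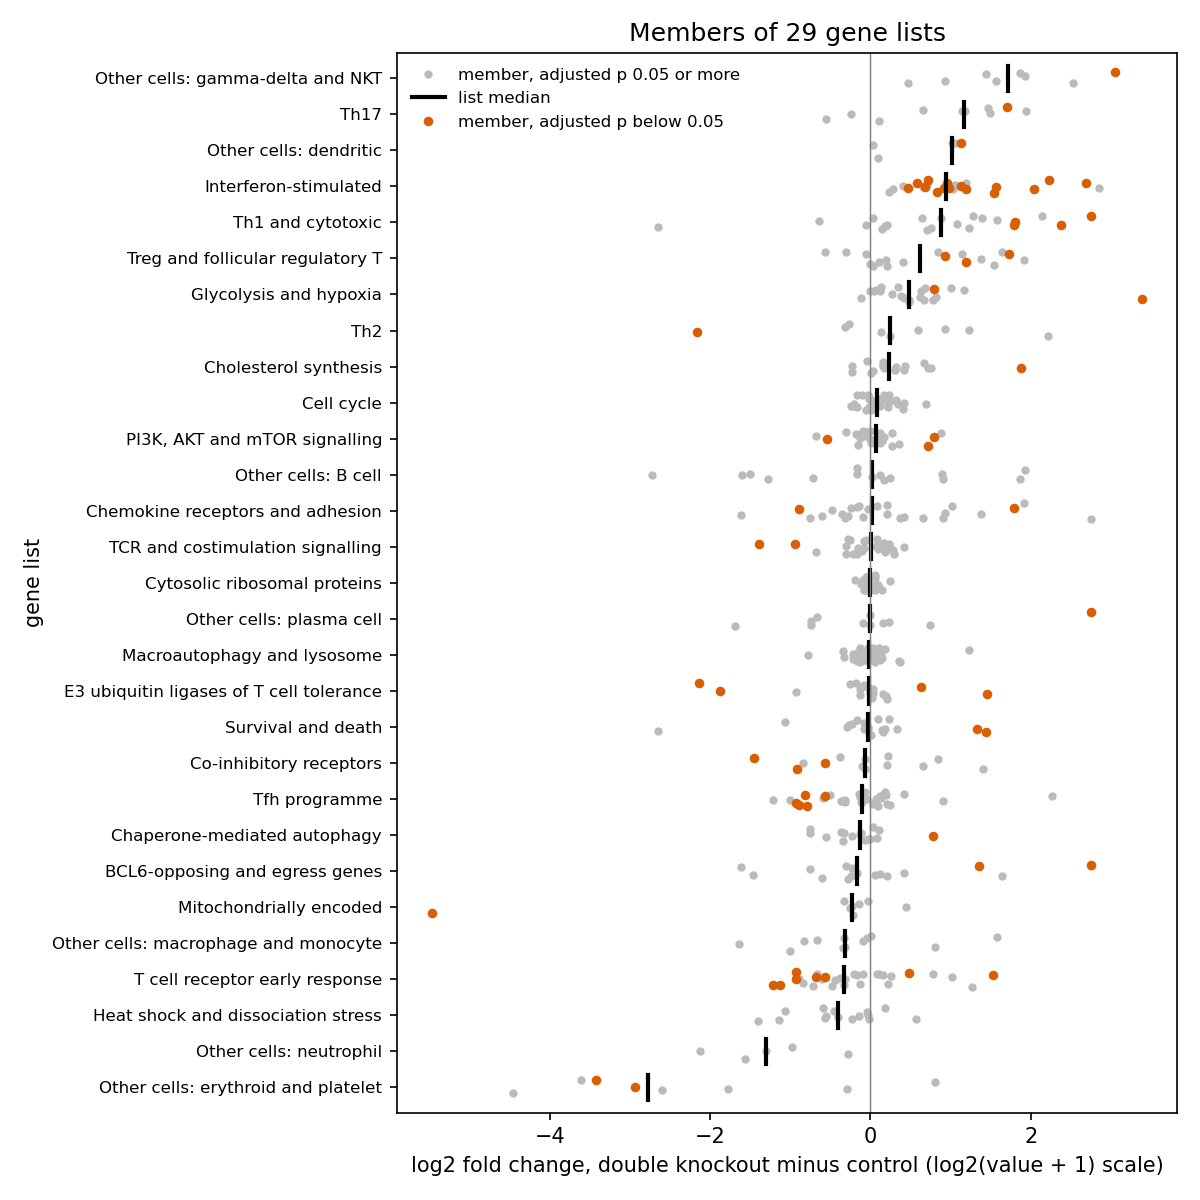
Log2 fold change (double knockout minus control, log2(value + 1) scale) of each measured member of the 29 tested gene lists, 1 row per list ordered by median; orange points passed the test, grey points did not, and black bars are list medians. All 26 interferon-stimulated genes lie to the right of 0, with a median of 0.94, whereas the medians of the cell cycle, ribosomal and macroautophagy lists lie between -0.02 and 0.08.

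Of 22 glycolysis and hypoxia genes, Pdk1 and Vegfa rose (4 over the list alone) and 20 had positive fold changes. The list had a median of 0.48 (camera adjusted p = 3.46e-05; adjusted p = 0.6 with an estimated correlation) and ranged from 0.23 to 0.66 with each library left out in turn. Vegfa was near the floor, at 20.5 ± 0.0522 against 1.3 ± 1.13. Of 18 cholesterol synthesis genes, 1 rose, none fell and 17 did not pass (1 rose over the list alone). The list median of 0.23 (camera adjusted p = 0.00846; adjusted p = 0.665 with an estimated correlation) lost its call without double knockout replicate 3 (adjusted p = 0.0577) or control replicate 1 (adjusted p = 0.073). In the list of survival and death genes the p53 targets Cdkn1a (1.44 ± 0.24) and Bbc3 (1.33 ± 0.24) rose and 19 of 21 did not pass (2 rose and 1 fell over the list alone; median -0.03, camera adjusted p = 0.97497). Bbc3 kept its call in 1 and Cdkn1a in 2 of the 6 fits that left out a library. None of 35 cell cycle genes passed, over all genes or over the list alone (median 0.08, camera adjusted p = 0.611). The libraries differed widely within the double knockout. Mki67 stood at 16174, 7630 and 26640 there and between 8397 and 10016 in the controls, and Mcm2 had 6244 ± 2638 against 4824 ± 746. Without double knockout replicate 2 the cell cycle list shifted up (median 0.48, camera adjusted p = 1.79e-08). Without replicate 3 it shifted down (median -0.30, adjusted p = 0.00106). Among 26 chemokine receptor and adhesion genes Cxcr3 rose and Cxcr4 fell (2 rose and 4 fell over the list alone; median 0.02, mean 0.25, camera adjusted p = 0.922).

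None of 39 cytosolic ribosomal protein genes passed, over all genes or over the list alone (median -0.01, mean 0.00, camera adjusted p = 0.922). Rpsa had 80362 ± 22561 against 66915 ± 11732. Of 8 mitochondrially encoded genes only mt-Nd3 fell (1 rose and 1 fell over the list alone; median -0.23, camera adjusted p = 0.075). These transcripts took between 2.59% and 3.35% of the reads of each library. No gene of the 15 in the heat shock and dissociation stress list passed, over all genes or over the list alone. The list shifted down, as the early response list did, and 13 members had negative fold changes (median -0.40, camera adjusted p = 0.0135; adjusted p = 0.665 with an estimated correlation). It lost its call without double knockout replicate 1 (median -0.12, camera adjusted p = 0.248) or control replicate 3 (median -0.26, camera adjusted p = 0.126). Its members with the smallest p were Dnajb4 (192 ± 90.2 against 379 ± 52.1) and Dnaja1 (5419.7 ± 1278 against 7923 ± 829.5). Hspa1a stood at 2779, 18534 and 12968 in the double knockout and at 20369, 22623 and 27045 in the controls (limma adjusted p = 0.288).

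Of 15 B cell genes, none passed over all genes (3 rose and 3 fell over the list alone), the median was 0.02 and the mean -0.13 (camera direction down, adjusted p = 0.922). S1pr2, also a Tfh gene, had 3953 ± 1028 against 2075 ± 327 and Mef2b 31 ± 8.68 against 7.7 ± 1.75. Of 11 plasma cell genes, Prdm1 rose (1 rose and 1 fell over the list alone; median -0.01, camera adjusted p = 0.777). None of 12 macrophage and monocyte genes passed (1 rose and 1 fell over the list alone; median -0.32, camera adjusted p = 0.498), with Cd68 at 347 ± 188 against 104 ± 14.6 and Vcam1 at 32.1 ± 15.7 against 100.4 ± 39.6. None of 5 neutrophil genes passed, over all genes or over the list alone (median -1.30, camera adjusted p = 0.132), with Ltf at 4.06 ± 6.27 against 14 ± 9.47 and Ngp at 5.19 ± 6.37 against 12.1 ± 6.9. Of 5 dendritic cell genes, Bst2, which is also in the interferon list, rose (1.13 ± 0.16; 1 over the list alone). The list median of 1.02 missed the threshold (camera adjusted p = 0.0509). It passed under 6 alternatives (adjusted p from 0.0192 to 0.0494). Of 8 gamma-delta and NKT cell genes, Trdc, the T cell receptor delta constant gene (ENSMUSG00000104876, chromosome 14, 54142851 to 54148868), rose from 905 ± 92.2 to 7946 ± 3593 (log2 fold change 3.05 ± 0.27, limma adjusted p = 0.00303; 4 rose over the list alone). The list median was 1.72 (camera adjusted p = 9.85e-05; adjusted p = 0.454 with an estimated correlation). Trdc passed with each library left out in turn. The erythroid and platelet list was lower (median -2.78, camera adjusted p = 0.000496; adjusted p = 0.552 with an estimated correlation). Of its 8 measured genes Hba-a1 fell from 83.4 ± 40.7 to 10.6 ± 7.13. Hba-a2, a near-identical copy whose reads cannot be told apart with certainty, had 50 reads over the control libraries and 2 over the double knockout, a ratio of 29.7 (95% counting interval 7.79 to 251.6; 5 fell over the list alone). Of the CD8 T and NK list 4 genes were measured, too few for a list test. Cd8b1 fell from 476 ± 48.7 to 137 ± 44.5 and Klrb1c, which encodes NK1.1, from 2467 ± 222 to 792 ± 387 (2 fell over the list alone, median -0.92). Cd8a, named outside the rule, had no reads in the controls and 1.88 ± 1.80 normalised counts in the double knockout. The fall of Cd8b1 was thus not matched by Cd8a.

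The largest rises by the fixed rule began with Xist, the long noncoding RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254), at 18100, 17308 and 12769 in the double knockout and 53.3, 970.4 and 12.9 in the controls (log2 fold change 7.46 ± 1.28, limma adjusted p = 0.0265). It missed the threshold with edgeR (adjusted p = 0.06), in the authors' deposited table (log2 fold change 0.46, adjusted p = 0.238), and without double knockout replicate 1 or control replicate 1. Mcam, which encodes an adhesion molecule (chromosome 9, 44134469 to 44142727, the direct neighbour of Cbl), had 918 ± 248 against 11.4 ± 13.3 (7.16 ± 1.02). Moxd1 had 316 ± 240 against 3.09 ± 2.26 (6.18 ± 0.62) and Gdpd3 had 2667 ± 1577 against 75.6 ± 108 (6.16 ± 0.99). With each library left out in turn Mcam ranged from 5.83 to 8.21 and Gdpd3 from 5.30 to 7.45; Mcam lost its call without double knockout replicate 1 (adjusted p = 0.0705), and Gdpd3 without that library (adjusted p = 0.0914) or control replicate 1 (adjusted p = 0.094). The authors' deposited table gives Mcam 0.63 and Gdpd3 0.59, with no adjusted p for either. It also gives smaller absolute log2 fold changes for other genes with few control reads, such as Platr11 (2.04 against 5.74 here) and Dcn (1.36 against 4.99). Genes with many control reads were affected too, such as Dtx1 (-1.21 against -2.13) and Kdm5d (-6.78 against -8.91). These estimates are therefore not like for like. Fxyd6, also on chromosome 9, rose from 3.54 ± 5.27 to 100.9 ± 42.2 and Scg2 from 2.85 ± 2.75 to 129.8 ± 105.4. Scg2 kept its call in 1 and Fxyd6 in 2 of the 3 fits with a library left out that kept them in the test. The long noncoding RNA Platr11 had 262 reads in the double knockout and 1 in the controls, a ratio of 221 (95% counting interval 39.3 to 8757), and Dcn, which encodes decorin, 180 and 1, a ratio of 152 (26.9 to 6027). Intervals of this kind cover counting error only. Dcn kept its call in 0 of the 3 fits with a library left out that kept it in the test. The limma adjusted p for Dcn ran from 0.0557 to 0.103 there and was 0.077 with a pseudocount of 10.

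The largest falls were Y-linked. Ddx3y had 3.21 ± 3.64 against 3402 ± 512 (log2 fold change -10.12 ± 0.66) and Eif2s3y 2.25 ± 2.62 against 1974 ± 188 (-9.61 ± 0.58). Uty had 1.118 ± 1.24 against 1354 ± 367 (-9.46 ± 0.48) and Kdm5d 2.94 ± 1.05 against 1864 ± 229 (-8.91 ± 0.28), with limma adjusted p of 0.000783 or less. The labels give no sex. By Xist and these Y-linked transcripts, the double knockout libraries had the pattern of female mice and the controls that of male mice. This followed the genotype groups in all 6 libraries, so no difference reported here can be separated from sex. With genes on X and Y left out of the test, 382 genes differed, but this only drops those genes and does not adjust the others for sex. Of the remaining falls, mt-Nd3 had 1 read in the double knockout and 171 in the controls, a ratio of 203 (95% counting interval 35.9 to 8058), and Gc, which encodes the vitamin D-binding protein, 1 and 149, a ratio of 177 (31.2 to 7027). Chst3 fell from 106.1 ± 58.2 to 5.56 ± 7.96 and Cd300lb from 89.6 ± 23.6 to 5.58 ± 7.24. Each kept its call in 1 of the 6 fits that left out a library.

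**Figure D3:**
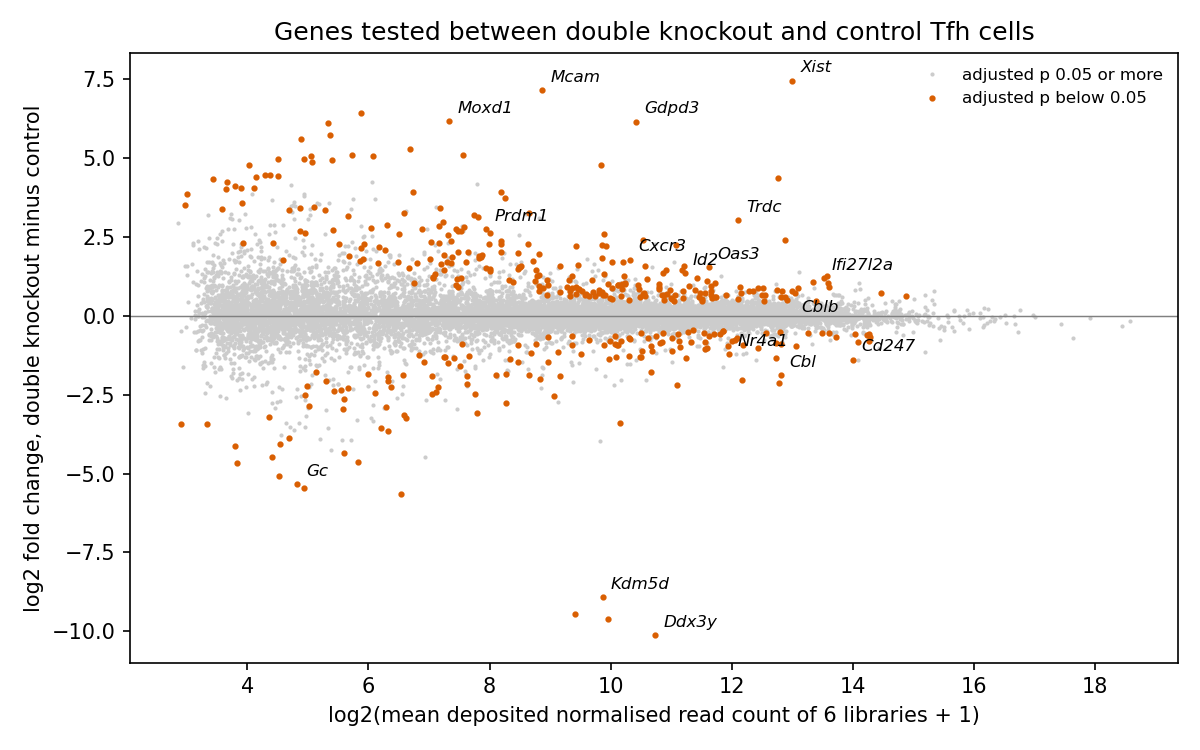
Log2 fold change (double knockout minus control) against log2 of the mean normalised read count of the 6 libraries plus 1, for the 13602 genes tested; orange points passed the test and labelled genes are named in the text. Xist and Mcam lie highest among the labelled genes, and the Y-linked genes Ddx3y and Kdm5d lie at -10.12 and -8.91.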

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

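The count of 398 genes (252 higher, 146 lower) stayed within 1.5 times with edgeR (405), pseudocounts of 0.5 (390) and 10 (462), no filter (443), a filter at 50 (343), TMM (397) or quantile scaling (420), receptor segments left out (365), and, both chosen after seeing the data, X and Y genes left out (382) and genes within 5 Mb of Cbl or Cblb left out (384). It was 1036 (644 higher, 392 lower) with DESeq2, which also called 397 of the 398, 993 (615 and 378) in the authors' deposited table, and 1368 (769 and 599) with library weights, where 56.2% of calls were higher against 63.3%; the cause was not tested. Leaving out X and Y genes only drops them and does not adjust the other genes for sex. Leaving out 1 library gave 58 to 498 genes, 33 to 254 higher and 13 to 244 lower. Same-numbered libraries of both groups had correlations of deviations of 0.07, 0.05 and 0.09. These values were small, but each library correlated best with its own number in the other group. The second principal component (17.7% of the variance) also ordered the libraries by number in both groups, at 4.09 and 2.26 for number 1, -30.9 and -32.6 for number 2 and 25.0 and 32.2 for number 3 (double knockout and control), so a shared factor stays open. With the replicate number as a block, 265 genes passed (170 higher, 95 lower), and only 221 of these were among the 398 of the main test. Of the named genes, Tigit, Gzma, Zeb2, Ahr, Cd200r1, Pdk1, Ddit4, Socs3, Rnf128, Vegfa, Cdkn1a, Bbc3, Klrb1c, Fxyd6, Scg2, Dcn and Hba-a2 lost their calls (adjusted p from 0.0506 to 0.0747). Of the 11 lists that camera called with its preset correlation, none passed with an estimated correlation (0 lists; 3 at an unadjusted p below 0.05) or with fry (0 lists; 8 at an unadjusted p below 0.05; smallest adjusted p = 0.0577), and ranks called 10.

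Among genes that had not passed, the sign turned with library weights for Bcl6 (-0.0730) and Il21 (-0.18), and with 1 library left out the ranges crossed 0 for Bcl6 (-0.0897 to 0.22), Pdcd1 (-0.19 to 0.0121), Icos (-0.12 to 0.0613), Il21 (-0.21 to 0.21), Maf (-0.0580 to 0.36) and Mcm2 (-0.0185 to 0.56); the cause was not tested. Some named genes that had not passed did so under alternatives. They were Optn, Dnajb4, S1pr2, Mef2b, Cd68 and Vcam1 with DESeq2, in the authors' table and with library weights; Ulk1 and Dnaja1 with weights; Optn, Dnajb4, S1pr2, Cd68, Vcam1 and Mki67 without double knockout replicate 2; and S1pr2 with edgeR, a pseudocount of 10, no filter and quantile scaling. Lists that gained a call were chaperone-mediated autophagy (weights, without double knockout replicate 3), mitochondrially encoded (weights, adjusted p = 0.0121; without double knockout replicate 2, 0.0466), chemokine receptors (without double knockout replicate 3, 0.0267), neutrophil (without control replicate 1, 0.0145), cell cycle (without double knockout replicate 2 or 3), ribosomal proteins (weights, 0.0486; without control replicate 3, 0.00547; both as higher) and dendritic (pseudocount of 10, weights, block, without double knockout replicate 3 or control replicate 3, genes near Cbl and Cblb left out). The cause was not tested. No named gene that passed changed sign under any alternative. Lists that had not passed also turned, read by the direction of the test, which can differ from the sign of the median: the chemokine receptor list (median 0.0203 without a filter and without X and Y genes, -0.12 with a filter at 50), the survival list (-0.0287 with a filter at 50, -0.0472 with quantile scaling, 0.0199 with library weights, -0.0287 with fry), the B cell list (0.17 with a filter at 50), the macrophage list (0.00823 with a filter at 50), the ribosomal list (0.0106 with quantile scaling, 0.10 with library weights), the BCL6-opposing list (0.0252 with library weights, -0.17 with fry), the plasma cell list (-0.0118 with fry) and the E3 ligase list (-0.00470 without genes near Cbl and Cblb). With 1 library left out, medians ranged from -0.38 to 0.15 for the BCL6-opposing list, -0.11 to 0.0620 for E3 ligases, -0.0424 to 0.00798 for macroautophagy, -0.30 to 0.48 for the cell cycle, -0.0637 to 0.0628 for survival, -0.0469 to 0.28 for chemokine receptors, -0.0893 to 0.13 for ribosomal proteins, -0.11 to 0.31 for B cells and -0.10 to 0.0334 for plasma cells. Among genes with few reads, Vegfa, Scg2, Hba-a2 and Dcn lost their calls in 2 or more of the 3 fits that kept them in the test with 1 library left out.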

Other observations

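The tests and names in this part were chosen after the results were seen, except the comparison with other splits of the libraries. Among genes outside the fixed lists that passed as higher were 5 that interferon can induce, picked by their values, without a count or test over such genes. Iigp1, an immunity-related GTPase, had 2266 ± 297 normalised counts against 778 ± 250.4, Gbp2 4542 ± 814 against 2209.8 ± 267 and Parp12 924 ± 14.6 against 385 ± 66.1. Ube2l6 had 553 ± 99.7 against 184 ± 14.8 and Ly6a 17005 ± 699 against 7325 ± 2150.1, with limma adjusted p between 0.00882 and 0.0191. Other abundant genes with clear differences were Hivep3, a zinc finger regulator, at 12629.6 ± 2269.6 against 2383 ± 577 (log2 fold change 2.42), the guanine exchange factor gene Farp1 (2.40), Plxnd1 (2.27) and Il10ra, which encodes the IL-10 receptor (1.59), all higher, and Sox4 (-2.53), Lmo4 (-2.04), Klf10 (-1.10) and Anxa3 (-3.40), all lower.

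Beside Xist, 3 X-linked genes known to escape X inactivation were picked, without a test over such genes. Kdm5c had 9175 ± 442 against 5338 ± 227 (limma adjusted p = 0.00832), Kdm6a 4061 ± 343 against 2389.6 ± 468 (adjusted p = 0.0404) and Eif2s3x 1837 ± 171 against 1186 ± 41.6 (adjusted p = 0.0256). Control replicate 2 had 970 normalised counts of Xist, against 53.3 and 12.9 in the other controls, together with Y-linked reads at the level of its group. It also had the highest control values of Gdpd3 (200.1 against 17.4 and 9.18), Mcam (26.0 against 0 and 8.27) and Fxyd6 (9.59 against 1.03 and 0), while Moxd1 was higher in control replicate 3 (5.51 against 2.74) and Platr11 had no reads in control replicate 2. The log2 fold change of Xist ran from 6.11 to 9.18 with each library left out in turn, and RNA of another sample in control replicate 2 was not tested. Anxa3, at 156 to 211 in the double knockout libraries, ranged from 1258 to 3323 in the controls.

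The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The split by genotype gave 398 genes, 252 higher and 146 lower, and was the only 1 of the 10 with as many; the highest of the other splits gave 0 in each of the 3 counts, with 116 to 1483 genes at an unadjusted p below 0.05 in limma against 2308 by genotype. For lists the genotype split gave 11 and the highest other split gave 13, and 3 of the 10 splits gave at least 11, so a count of lists called at the preset correlation did not set the genotypes apart. For the interferon list alone, the absolute median was 0.94 by genotype and at most 0.54 in any other split. Its camera p at the preset correlation was 1.49e-22 by genotype and as low as 1.13e-13 in another split. In other splits the smallest camera p was 3.97e-27 for the ribosomal list and 7.38e-22 for the cell cycle list. Very small camera p-values thus also arose from groupings other than genotype. Among the other called lists, another split gave a larger absolute median for the Tfh programme (0.22 against 0.11), Th1 and cytotoxic (0.99 against 0.88), glycolysis (0.53 against 0.48) and heat shock lists (0.4022 against 0.4001). The camera p was smallest by genotype for the interferon, Th17, early response and gamma-delta lists alone of the 11, and for glycolysis 4 of the 10 splits had a p as small, the genotype split among them.

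The interferon-stimulated list was higher in all 3 double knockout libraries. It was not carried by double knockout replicate 2, which stood apart in Foxp3, since its median without that library was 0.84. RNA of B cells, macrophages, neutrophils or dendritic cells, which the sort on CD4 and TCR beta would remove, is argued against by their 33 markers found in no other list: their summed increase was 0.0478 of that of the interferon list (1494 against 31262 normalised counts), with the larger increases at Cd74 (1751 against 930), Cybb (1377 against 849) and Cd68 (347 against 104), and none at Lyz2 (30.5 against 51.8) or H2-Aa (92.1 against 93.5). The argument is weaker for dendritic cells, whose markers Cst3 (1420 against 1332), Zbtb46 (45.4 against 22.5) and Tcf4 (333 against 326) all increased. The dendritic cell list had a median of 1.02 (camera adjusted p = 0.0509), but it includes Bst2, which is also in the interferon list. The sex of the mice stays open and cannot be told apart from genotype, because 0 of the 6 libraries had Xist and Y-linked reads that departed from their genotype group. Other T cells in the sort were not tested, so that an effect of the genotype on interferon responses in Tfh cells remains a hypothesis.

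Called genes gathered around Cbl. Apart from Cbl, 10 of the 72 tested genes within 5 Mb of it passed (13.9%; Ubash3b, Sorl1, Mcam, Nlrx1, Ube4a, Scn2b, BC049352, Il10ra, Fxyd6 and Rexo2), against 2.66% elsewhere, and 0.101% of 11859 runs of 72 neighbouring genes held as many calls, which argues against an even spread. An effect on direct neighbours alone is argued against as well, because 8 of 50 genes between 0.5 and 5 Mb passed (Fisher's exact test, one-sided, p = 5.56e-05). A candidate explanation is DNA of another mouse strain kept next to the targeted gene through breeding; around Cblb 2 of 20 genes passed (Cd47 and Pcnp; Fisher's exact test, one-sided, p = 0.102), and gene totals carry no sequence variants, so this cannot be told apart from distant effects of the deletion. Changes in genes such as Ubash3b and Il10ra may therefore come from their place on chromosome 9 and not from loss of the ligases.

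Along the T cell receptor alpha and delta locus on chromosome 14, V segments of the alpha chain far from the J segments had a median log2 fold change of -1.82 (5′ portion) and near ones of -0.09, but 5 of 57 V segments passed as lower and 2 as higher, and 1 and 3 of 50 J segments. The log2 fold changes had a rank correlation with position of 0.74 over 57 V segments and -0.58 over 50 J segments (permutation p = 1e-05 for both, the smallest that 100000 permutations can give, and 1e-05 after adjustment over the 2; segments are not independent replicates, and V segment families share reads). Gamma-delta T cells, which the sort on TCR beta would remove, stay open. Tcrg-C1, Tcrg-C2 and Tcrg-C4 together increased by only 0.013 of the increase in Trdc. How reads shared within this gene family were counted is not known, so the low share cannot exclude such cells. Tcrg-C2 rose from 20.3 to 77.5. Double knockout replicate 2 had the highest values of Trdc (12060), Tcrg-C1 (62.3), Tcrg-C2 (160.6) and Tcrg-C4 (74.6). All 8 measured genes of the gamma-delta and NKT cell list had positive fold changes. Expanded clones in single mice are argued against for V segments, where each double knockout library had a correlation of 0.67 to 0.71 against the controls and each control one of -0.05 to 0.12 against the other controls, but stay open for J segments, where the double knockout libraries ranged from -0.57 to -0.36 and control replicate 3 alone had -0.56. A hypothesis is that double knockout cells went through fewer successive rearrangements of the alpha locus. It was formed from these V and J segment values, so they do not test it. How it would bear on Trdc, which lies between the V and J segments, was not tested. Another strain's alleles at this locus, sex and differences in gene counting between near-identical segments were not tested either.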
